A study of Homo sapiens with 8 samples.

How the data were processed

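RNA from SaOS-2 cells, an established human osteosarcoma cell line, was measured on 8 Agilent 1-colour arrays, and the deposited files of all 8 were analysed. Per the labels, 3 arrays held cells after 1 week in maintenance medium, 2 held cells after 2 weeks in differentiation medium and 3 held cells after 3 weeks in differentiation medium. Groups and replicate numbers were taken from the titles of the samples. Per the labels' protocols, 200 ng of total RNA was copied from oligo-dT primers and transcribed into Cy3-labelled cRNA. Priming of this kind favours the 3′ ends of polyadenylated transcripts. The labels do not state whether replicates were separate cultures, and the series design text says only that experiments were in triplicate or duplicate. The p-values therefore measure the spread between these samples, which may be technical.

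Per the file headers, the deposited intensity values were extracted with Agilent Feature Extraction 10.7.3.1. The processed intensity of a spot had its spatial background subtracted and a trend across the array removed, per the file headers, with no scaling between arrays. Spots close to background carried a small surrogate value in place of their own, which makes folds against a dim group unreliable. The deposited files also held other columns, the flags of the extraction software for background, saturation and outlier spots, and the raw mean and local background intensity. The value table deposited for the whole series, whose scale and centring no label states, equalled the processed intensity of each array exactly (largest absolute log2 ratio 0). Its column medians ran from 37.0 to 57.0, so it was on the linear scale and uncentred, and it moved nothing when used as an alternative. There were 0 columns of samples outside the series.

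The arrays held 50599 distinct non-control probes, of which 902 were spotted 10 times. Control spots and outlier-flagged spots were left out, and 20 probes with no remaining spot on some array were dropped. Spots of 1 probe were averaged. Each value was the log2 processed intensity minus the array's 75th percentile over non-control probes. A probe was kept if it was well above background on every array of at least 1 of the 3 groups, which left 29722 probes. The probe with the highest mean over all 8 arrays stood for each gene name of the array design, giving 21974 genes. Of the 5477 genes with more than 1 kept probe, 77 had probes called in opposite directions in the comparison of the media, and none of these is among the genes named by rule. Of the 30 genes named by rule that had more than 1 kept probe, 14 had probes whose folds between the media differed by over 1.5 times and 5 others had probes that differed in sign or call. Where the value of such a gene between the media is printed, those of its other probes stand beside it.

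Gene names were updated through accessions, or through symbols where no accession matched, with a name table of assembly GRCh38.p14 used for names only. Of all probes, 31412 matched a current symbol (28174 by accession, 2618 by symbol and 620 by a single older symbol) and 19187 kept the name in the files. Of the genes tested, 16124 had a current symbol, and 25 symbols were carried by more than 1 gene name. Probe positions are those of the files, on hg19, also called GRCh37. Gene models of that build were not used here, so probes were not assigned to exons or untranslated regions.

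Groups were compared on the log2 scale with lmFit and eBayes in limma 3.58.1 (R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparison of the media fitted 5 differentiation arrays against 3 maintenance arrays as 2 groups. The comparisons of 2 weeks and of 3 weeks with maintenance medium, and of 3 with 2 weeks, came from 1 fit of all 3 groups. In the fit of 2 groups, the difference between 2 and 3 weeks counted as spread, which widened the errors of genes that differed between these times. Errors given with a fold change are standard errors of the fit.

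Where a gene was not well above background on any array of the dimmer group in any of its probes, and was so on at least 1 array of the brighter group, the fold is given as a bound. The bound set the bright group's mean against a dim mean in which each array contributed the higher of 2 values, the lowest signal among its probes well above background and the dim probe's own signal.

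A total of 21 gene lists were tested with camera in limma, with a preset correlation of 0.01, against all other genes, and adjusted over the lists within a comparison. Of these, 5 were primary (osteoblast, osteocyte and mineralisation, glucocorticoid response, proliferation, collagen and matrix), 11 covered other programmes and 5 were markers of other cell types. The direction of a list is that of its camera test. Each test was repeated with the correlation estimated from the arrays. The lists, the tests, the primary comparisons and the rule for named genes were fixed before the data were examined.

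Named genes were chosen by rule. The first part took called genes with a symbol, well above background on every array of the higher group and with no overlap between the groups' arrays. From these it took the 10 largest rises and 10 largest falls between the media, the 8 and 8 largest at each time against maintenance, and the 5 and 5 largest between 3 and 2 weeks. The second part took up to 4 members of each list with the smallest p between the media. The third part named a fixed set of 16 bone, glucocorticoid and proliferation genes. The rule gave 121 genes, of which 1 is not reported here, and any other gene in the text is said to have been chosen after its values were seen.

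The fits were tested on simulated data made from the real genes' means and spreads, with 200 of 21974 genes changed. For differentiation against maintenance medium, 35.8% of genes changed by 0.5 on the log2 scale were recovered, 86.6% of those changed by 1 and 98.5% of those changed by 2, with 11 unchanged genes called. For 2 weeks against maintenance the shares were 62.7%, 82.1% and 95.5% with 9 unchanged genes called, and for 3 weeks 56.7%, 82.1% and 95.5% with 11. For 3 against 2 weeks they were 52.2%, 86.6% and 95.5% with 10. The real comparisons called 40.6% to 63.1% of genes, far more than the 200 changed here. The shares recovered therefore describe this setting and not the sensitivity in the data. The number of arrays limits the precision.

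The alternatives tried were quantile normalization, scaling to the median, normexp background correction with an offset of 50, no filter on dim probes, only probes above background on all arrays, the mean of a gene's probes, the deposited value table, a trended and robust variance model, array weights, other samples in the fit, the replicate number as a block, each array left out in turn, an estimated correlation and the fry test. All arrays were on 1 slide and were scanned at 1 time, so neither could be fitted as a block. The arrays lay in 2 rows of 4, and the row was added as a block after the data were seen. Scaling by spike-in probes was not run, because most of them were at background. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.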

Results

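SaOS-2 cells derive from a human osteosarcoma and keep many properties of osteoblasts, the bone-forming cells. Genome-wide transcript levels were compared between 3 arrays of cells kept for 1 week in maintenance medium and 5 arrays of cells in differentiation medium, 2 taken at 2 weeks and 3 at 3 weeks. Both media held 10% serum. Differentiation medium also held dexamethasone at 100 nM, a synthetic glucocorticoid, ascorbic acid at 50 µM, a cofactor of collagen hydroxylation, and β-glycerophosphate at 10 mM, a phosphate source for mineral. Medium and time in culture changed together, so the comparisons with maintenance medium do not separate them. Between 55.5% and 62.6% of probes per array were well above background, and the 75th percentile of processed intensity ran from 453 to 663. Both were lower in differentiation medium, with at most 58.5% of probes and a 75th percentile of at most 555, against at least 58.9% and 595 in maintenance medium. Scaling each array set these percentiles equal. The median processed intensity of negative control spots was not lower in differentiation medium (4.49 to 4.93, against 4.33 to 4.67 in maintenance medium). Scaling therefore did not align the background level, and differences of genes near background can hold a shift between the media. No spot was saturated.

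The groups were well apart. Pearson correlations across genes, which are not independent replicates, were 0.994 to 0.997 between arrays of 1 group. They were 0.966 to 0.968 between maintenance medium and 2 weeks, 0.984 to 0.987 between 2 and 3 weeks, and 0.954 to 0.958 between maintenance medium and 3 weeks. The first principal component held 72.9% of the variance and ordered the groups from maintenance medium through 2 weeks to 3 weeks. The second held 13.1% and set the 2-week arrays apart from the rest.

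**Figure D1:**
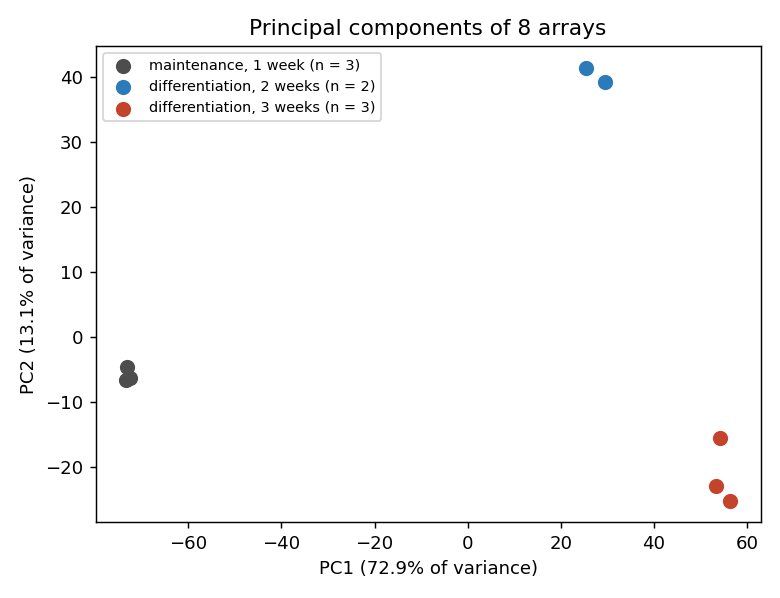
Scores of the 8 arrays on the first (72.9% of variance, x axis) and second (13.1%, y axis) principal components of the normalised log2 signals, in arbitrary units, coloured by group. The maintenance arrays lie between -73.4 and -72.4 on the first component, the 2-week arrays at 25.5 and 29.5, and the 3-week arrays between 53.4 and 56.4.

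The first comparison asked which genes differ between differentiation and maintenance medium, the contrast in the title of the series. In differentiation medium the largest rises included IL1R2, a decoy receptor for interleukin-1, SOST, which encodes the osteocyte product sclerostin, and WIF1, a secreted Wnt antagonist. IL1R2 was at least 88.9-fold higher (log2 difference 8.39 ± 0.10, limma adjusted p = 8.2e-09) and was not well above background on any maintenance array. SOST rose 137-fold (log2 7.09 ± 0.88) and WIF1 88.8-fold (log2 6.47 ± 0.24), with limma adjusted p of 4.7e-04 and 8.0e-07. The largest falls included IGFL3, at least 31.7-fold lower (log2 -6.69 ± 0.18), and CNN1, the smooth muscle protein calponin (log2 -5.94 ± 0.53). NTRK3, the neurotrophin-3 receptor, fell by 5.90 ± 0.19 on the log2 scale, and its 3 other kept probes were also lower (-5.78, -4.98 and -2.21). All of these separated the 5 differentiation arrays from the 3 maintenance arrays with no overlap.

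Other large rises were in C1QTNF8, at least 47.8-fold, ANGPTL1, at least 36.5-fold, and RIPOR3, listed as FAM65C on the array, at least 21.0-fold. COL13A1, a membrane collagen, rose by 5.93 ± 0.21 and DAPL1 by 5.65 ± 0.07 on the log2 scale (3.36 in its other probe). DPEP1 (log2 6.25 ± 0.60) and FGD4 (log2 5.39 ± 0.61) were well above background on 1 of the 3 maintenance arrays. Without maintenance replicate 1 they differed by 7.12 and 6.07, and without maintenance replicate 3 FGD4 differed by 4.75. The 2 other probes of FGD4 differed by 3.01 and 2.04. Among the falls, ABTB3, listed as BTBD11, was at least 11.9-fold lower, and CACNB2, a calcium channel subunit, at least 10.3-fold lower in the probe used, while its other probe had a fitted log2 difference of -2.62. F2RL1, ERICH5 (listed as C8orf47) and the dopamine receptor DRD2 had log2 differences of -6.05, -5.55 and -5.29, each above background on 1 of the 2 2-week arrays and on 0 of the 3 3-week arrays. LIPG, an endothelial lipase, had a log2 difference of -5.29 ± 0.96, and of -2.97 with no call with the slide row as a block. CGB3, listed as CGB, fell by 5.45, and its near-identical paralogs may share its probe.

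The probes of IL1R2, SOST and WIF1 lay on chromosome 2 at 102632505 to 102636150, chromosome 17 at 41831968 to 41832027 and chromosome 12 at 65444732 to 65444791 of hg19. Those of IGFL3, CNN1 and NTRK3 lay on chromosome 19 at 46623454 to 46623513, chromosome 19 at 11661005 to 11661064 and chromosome 15 at 88520610 to 88520669.

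In all, limma called 9914 of 21974 genes, 4541 higher and 5373 lower in differentiation medium, and 2287 of these by at least 2-fold (1001 higher, 1286 lower). At an unadjusted p under 0.05 it called 11639. A total of 441 called genes had only a bound on their fold. With the slide row of each array as a block, fewer genes were called. That fit sets the 3 maintenance arrays against the 1 differentiation array of their row. It also still counts the difference between 2 and 3 weeks as spread, and how much each lowered the count was not tested. Normexp background correction with an offset of 50 left 1310 genes at 2-fold or more and a log2 difference of 4.50 for IL1R2. The offset compresses folds of dim probes, but this setting also started from the raw mean and local background intensities. How much each lowered these values was not tested.

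Genes of the osteoblast lineage had the highest median of the 21 lists between the media. At 3 weeks against maintenance medium their median (1.20) was below those of 2 other lists. These were interferon-stimulated genes (1.42) and genes of endoplasmic reticulum stress and amino acid supply (1.30). Between the media, 21 of the 25 osteoblast genes measured rose and 1 fell (22 and 1 adjusted over the list alone). Their median log2 difference was 1.24 (camera adjusted p = 6.7e-11 in limma, adjusted p = 0.0299 with an estimated correlation). IFITM5, a bone-restricted membrane protein, rose by 3.89 ± 0.05 and PHOSPHO1, a phosphatase of matrix vesicles, by 3.38 ± 0.05. IBSP, bone sialoprotein, rose by 3.46 ± 0.33 and the transcription factor SP7, osterix, by 1.31 ± 0.10 (0.57 in its other probe). ALPL, the tissue-nonspecific alkaline phosphatase, rose less, by 0.82 ± 0.07 (limma adjusted p = 8.3e-05), and COL1A1 by 0.37 ± 0.08. BGLAP, osteocalcin, differed by -0.17 ± 0.12 (limma adjusted p = 0.26). SPP1, osteopontin, rose by 4.29 ± 1.33 (limma adjusted p = 0.032). Its wide error held the difference between 1.52 at 2 weeks and 6.13 at 3 weeks, and the call was lost when any 1 maintenance or 3-week array was left out (log2 3.80 to 4.36). Without 2-week replicate 1 or 2 it differed by 5.01 or 4.95. RUNX2, the master regulator of osteoblasts, differed by 0.19 ± 0.06 (limma adjusted p = 0.035), but by -0.012 with no call in its other probe. The call was lost in 10 of 20 alternatives, among them those without maintenance replicates 1 or 2 (0.14 and 0.19), 2-week replicate 1 (0.17) or 3-week replicates 2 or 3 (0.17 and 0.19). With the slide row as a block the calls of RUNX2 (0.23), SPP1 (1.42) and COL1A1 (0.24) were lost.

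Osteocyte and mineralisation genes went both ways. Of 14 measured members, 5 rose and 6 fell (5 and 6 adjusted over the list alone), with a median of -0.03, a mean of 0.76 and a downward camera test (adjusted p = 0.972). Besides SOST, MEPE, an osteocyte matrix phosphoglycoprotein, rose by 3.33 ± 0.54 and the Wnt antagonist DKK1 by 1.58 ± 0.17. PHEX, a phosphate-regulating endopeptidase, was at least 2.61-fold higher and was well above background on the 3 3-week arrays only. With a block for the slide row, the calls of MEPE (2.26) and PHEX were lost. ANKH, a pyrophosphate transporter, and the adhesion receptor CD44 were lower (log2 -0.99 and -1.27), but the other CD44 probe differed by -0.17 with no call. DMP1 was not tested, because its 1 probe was well above background on 0 arrays.

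Glucocorticoid response genes rose on balance, with 12 of 27 measured members higher and 6 lower (14 and 7 adjusted over the list alone). Their median log2 difference was 0.29 (camera adjusted p = 0.0096 in limma, adjusted p = 0.299 with an estimated correlation). ZBTB16 rose by 4.23 ± 0.16, TSC22D3, the leucine zipper protein GILZ, by 3.59 ± 0.12, and FKBP5, a co-chaperone of the glucocorticoid receptor, by 2.38 ± 0.07. The clock gene PER1 rose by 1.83 ± 0.09. SGK1, a kinase named for its induction by serum and glucocorticoids, fell by 3.05 ± 0.09 (limma adjusted p = 2.8e-07) and had no other measured probe.

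Proliferation genes fell. Of 38 measured members, 26 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 1.8e-04 in limma, adjusted p = 0.649 with an estimated correlation). The log2 differences of MKI67, the mitotic cyclin CCNB1, the topoisomerase TOP2A and the kinesin KIF20A were -1.09 ± 0.25, -1.35 ± 0.26, -1.35 ± 0.26 and -1.23 ± 0.24. With the slide row as a block, and so 1 differentiation array at 2 weeks against maintenance medium, the list was not called in limma (median -0.48, adjusted p = 0.284), nor were MKI67 (-0.55), CCNB1 (-0.79), TOP2A (-0.82) and KIF20A (-0.72).

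Collagen and matrix genes showed no common direction, with 16 of 34 higher and 9 lower (17 and 9 adjusted over the list alone, median 0.27, camera adjusted p = 0.199 in limma). COL24A1, a fibrillar collagen, rose by 2.95 ± 0.07, the proteoglycan DCN, decorin, by 4.13 ± 0.15 and COL5A2 by 1.09 ± 0.07, while FBN1, fibrillin, fell by 1.86 ± 0.09.

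Of the other 11 programmes, 3 rose and 3 fell. Wnt targets and regulators rose, with 13 of 24 higher and 1 lower (14 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 6.4e-05 in limma, adjusted p = 0.0299 with an estimated correlation). They included SP5 at 1.39 and APCDD1 at 1.57, with WIF1 the largest. Genes of endoplasmic reticulum stress and amino acid supply rose, with 15 of 25 higher and 1 lower (15 and 1 adjusted over the list alone, median 1.10, camera adjusted p = 1.3e-06 in limma, adjusted p = 0.221 with an estimated correlation). The stress transcription factor ATF4 rose by 1.24 and the transcription factor CEBPB by 1.06. Interferon-stimulated genes rose, with 16 of 27 higher and 1 lower (18 and 1 adjusted over the list alone, median 0.92, camera adjusted p = 2.6e-04 in limma, adjusted p = 0.642 with an estimated correlation). OASL was at least 32.8-fold higher, the RNA sensor RIGI, listed as DDX58, rose by 0.48 (1.29 in its other probe), and HERC5 fell by 0.41.

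Hypoxia and glycolysis genes fell, with 20 of 24 lower and 1 higher (20 and 1 adjusted over the list alone, median -0.90, camera adjusted p = 1.3e-06 in limma, adjusted p = 0.160 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase, had a log2 difference of -1.91, the mitophagy receptor BNIP3 of -1.61 and the glycolytic regulator PFKFB3 of -1.24, with -0.22 and no call in its other probe. Sterol and lipid synthesis genes fell, with 10 of 26 lower and 0 higher (10 and 0 adjusted over the list alone). Their median was -0.44, or -0.42 with dim members at their bound (camera adjusted p = 0.0042 in limma, adjusted p = 0.642 with an estimated correlation). FDFT1, squalene synthase, was lower (log2 -0.87). Metallothioneins fell by small amounts, 6 of 8 being lower and 0 higher (6 and 0 adjusted over the list alone, median -0.26, camera adjusted p = 0.0319 in limma, adjusted p = 0.642 with an estimated correlation). MT1E and MT1M were lower (log2 -0.52 and -0.69), but near-identical paralogs of this family may share probes, so its members may not be separate measurements. With the slide row as a block, the interferon, sterol and metallothionein lists were not called in limma (medians 0.28, -0.09 and -0.17, adjusted p = 0.230, 0.525 and 0.226), nor were RIGI (0.37), FDFT1 (-0.39), MT1E (-0.41) and MT1M (-0.38). The metallothionein call was also lost with scaling to the median (-0.22) and without maintenance replicate 1 (-0.24).

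The remaining 5 programmes were not called by camera in limma. Matrix-degrading enzymes and their inhibitors had 9 of 20 higher and 7 lower (10 and 8 adjusted over the list alone, median 0.23, adjusted p = 0.400), with MMP7, matrilysin, higher by 4.21 ± 0.31 and the protease PLAU lower (-0.997 with no call in its other probe). BMP and TGF-β targets had 7 of 23 higher and 11 lower (7 and 11 adjusted over the list alone, median -0.29, adjusted p = 0.540). ID3, a BMP target, rose by 1.44 and BAMBI by 1.12, while the TGF-β-induced genes TGFBI and PMEPA1 were lower (log2 -1.31 and -1.54). Inflammatory genes had 3 of 18 higher and 6 lower (3 and 8 adjusted over the list alone, median -0.12, adjusted p = 0.374). The cytokines IL11 and LIF were lower (log2 -3.70 ± 0.11 and -2.78 ± 0.12), but the other LIF probe, above background on 4 arrays, differed by -0.50 with no call. NFKBIA, an inhibitor of NF-κB, rose by 1.14. Targets of p53 had 7 of 25 higher and 6 lower (8 and 8 adjusted over the list alone), with a median of -0.0069, a mean of 0.15 and an upward test (adjusted p = 0.918). BBC3 rose by 1.89 and the cell-cycle inhibitor CDKN1A by 1.07. Clock genes had 6 of 18 higher and 7 lower (6 and 7 adjusted over the list alone), with a median of -0.04, a mean of 0.09 and an upward test (adjusted p = 0.834). NPAS2 rose by 2.51 ± 0.23.

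Among markers of other cell types, only the smooth muscle and myofibroblast list was called by camera in limma. Of its 10 measured members, 7 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.80, adjusted p = 7.5e-04, adjusted p = 0.160 with an estimated correlation). CNN1 was joined by MYOCD, a smooth muscle coactivator, at -3.79 ± 0.16, TAGLN at -2.75 ± 0.11 and ACTA2 at -1.38 ± 0.12. Chondrocyte markers had 5 of 16 higher and 3 lower (5 and 4 adjusted over the list alone), with a median of -0.04, a mean of 0.84 and an upward test (adjusted p = 0.369). COL11A2 rose by 4.31 ± 0.13 (4.45 and 3.47 in its 2 other probes) and the hedgehog ligand IHH by 3.64 ± 0.09, while SOX9, the chondrocyte transcription factor, fell by 1.71 ± 0.20. PTH1R, which is also in the osteoblast list, rose by 3.42 ± 0.18 (1.90 in its other probe). Adipocyte markers had 1 of 10 higher and 4 lower (1 and 4 adjusted over the list alone, median -0.21, adjusted p = 0.605), with the fatty acid receptor CD36 higher by 2.41 and the transcription factor CEBPA lower (log2 -1.84). Blood and osteoclast markers had 1 of 10 higher and 2 lower (0 and 2 adjusted over the list alone, median -0.09, adjusted p = 0.816). Endothelial and epithelial markers had 3 of 8 higher and 3 lower (3 and 3 adjusted over the list alone, median 0.13, adjusted p = 0.540).

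Camera with the preset correlation called 10 of the 21 lists between the media, 5 up and 5 down. With the correlation estimated from the arrays, 2 of these calls held, those of the osteoblast and Wnt lists. In the other 3 comparisons none held, as set out with their lists. Between the media, the difference between 2 and 3 weeks counted as spread and so entered the estimate. The estimated correlation was 0.986 for proliferation and 0.913 for interferon-stimulated genes there, against 0.469 and 0.210 in the fit of 3 groups. For osteoblast genes it was 0.048 against 0.187. Which calls held between the media therefore depends in part on how the groups were fitted.

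**Figure D2:**
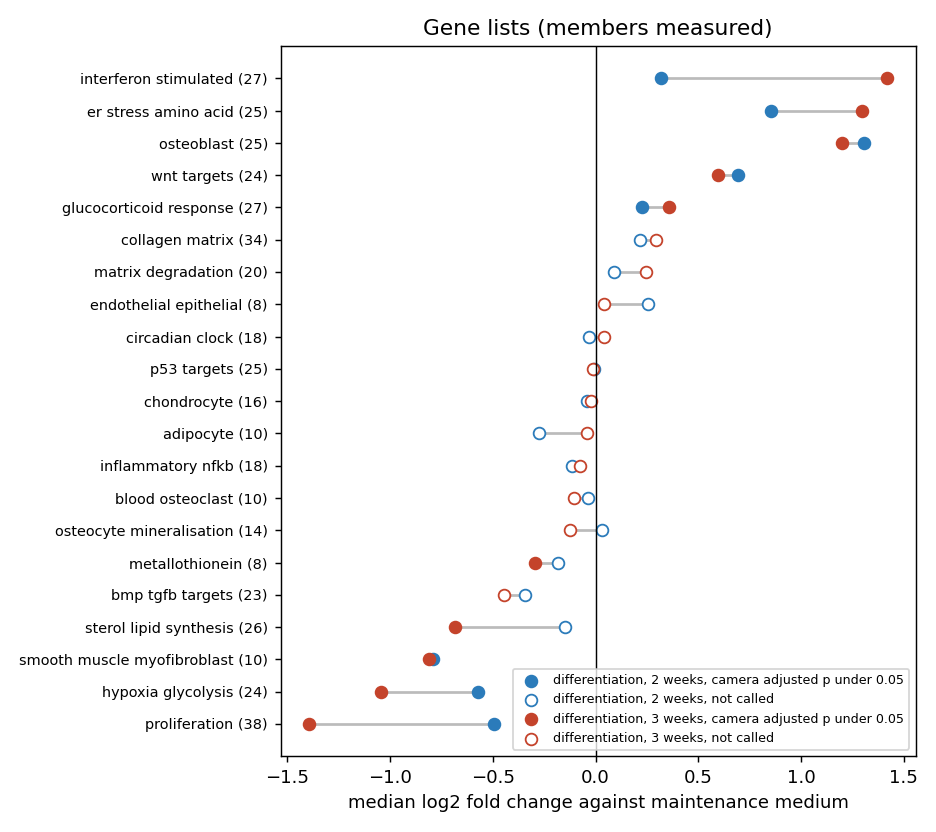
Median log2 fold change of each of the 21 gene lists against maintenance medium (x axis) at 2 weeks (blue) and at 3 weeks (red) of differentiation medium, with the number of measured members beside each name. Filled points had a camera adjusted p under 0.05 with the preset correlation. The interferon-stimulated list moved from 0.32 to 1.42 and the proliferation list from -0.49 to -1.39.

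The next comparisons took 2 weeks and 3 weeks of differentiation medium against maintenance medium one at a time. At 2 weeks IL1R2 (at least 81.8-fold), FGD4 (log2 6.14 ± 0.67), WIF1 (5.99 ± 0.06) and DPEP1 (5.78 ± 0.77) were among the largest rises, and PNOC, the precursor of nociceptin, rose by 5.52 ± 0.14. Without maintenance replicate 1 FGD4 differed by 6.82 and DPEP1 by 6.65, and without maintenance replicate 3 FGD4 differed by 5.49. Its 2 other probes differed by 3.68 and 3.12. IGFL3 was at least 34.0-fold lower, and the receptor kinase ROS1 fell by 5.12 ± 0.21. At 3 weeks SOST had risen by 8.31 ± 0.06 and OASL, an antiviral protein induced by interferon, was at least 62.2-fold higher, while ALDH1A3, which makes retinoic acid, fell by 5.67 ± 0.06 and F2RL1 was at least 32.1-fold lower. PHEX was at least 4.00-fold higher at 3 weeks. BGLAP was lower at 2 weeks by 0.38 and differed by -0.035 at 3 weeks, where limma did not call it.

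At 2 weeks limma called 10799 genes, 4947 higher and 5852 lower, with 2026 at 2-fold or more and 496 known only as bounds. At 3 weeks it called 13855, 6470 higher and 7385 lower, with 2872 at 2-fold or more and 628 known only as bounds. With the slide row as a block the 3-week count was 8699, since the row effect then rests on the pair of 2-week arrays. With normexp the counts at 2-fold or more were 1106 and 1688, and with probes above background on all arrays the 2-week count was 1343.

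By their median, osteoblast genes were near their full difference at 2 weeks, with 21 of 25 higher and 2 lower (22 and 2 adjusted over the list alone, median 1.30, camera adjusted p = 2.5e-11 in limma, adjusted p = 0.138 with an estimated correlation). Their mean was 1.39 at 2 weeks and 1.77 at 3 weeks. At 3 weeks 23 were higher and 1 lower (23 and 1 adjusted over the list alone, median 1.20, camera adjusted p = 2.2e-10 in limma, adjusted p = 0.171 with an estimated correlation). Proliferation genes fell at both times. At 2 weeks 26 of 38 were lower and 11 higher (26 and 11 adjusted over the list alone, median -0.49, camera adjusted p = 0.0130 in limma, adjusted p = 0.636 with an estimated correlation). At 3 weeks 36 were lower and 0 higher (36 and 0 adjusted over the list alone, median -1.39, camera adjusted p = 4.9e-13 in limma, adjusted p = 0.274 with an estimated correlation). Interferon-stimulated genes rose at both times. At 2 weeks 16 of 27 were higher and 4 lower (16 and 4 adjusted over the list alone, median 0.32, camera adjusted p = 0.0038 in limma, adjusted p = 0.567 with an estimated correlation), and at 3 weeks 25 were higher and 2 lower (25 and 2 adjusted over the list alone, median 1.42). The 3-week test gave a camera adjusted p of 2.4e-10 in limma, and adjusted p = 0.171 with an estimated correlation. Glucocorticoid response genes rose at 2 weeks, with 14 of 27 higher and 5 lower (14 and 6 adjusted over the list alone, median 0.23, camera adjusted p = 0.0115 in limma, adjusted p = 0.296 with an estimated correlation). At 3 weeks 15 were higher and 7 lower (15 and 7 adjusted over the list alone, median 0.36, camera adjusted p = 0.0043 in limma, adjusted p = 0.187 with an estimated correlation). Osteocyte and mineralisation genes were not called at either time, with medians of 0.03 and -0.13, means of 0.49 and 0.94 and upward tests. Camera called 8 lists at 2 weeks and 10 at 3 weeks, and with an estimated correlation 0 at either time (3 and 5 at an unadjusted p under 0.05), the lowest adjusted p being 0.0831 and 0.171.

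The calls at both times overlapped. limma called 8782 genes in the same direction at 2 and 3 weeks, 4014 higher and 4768 lower, and 485 in opposite directions. In 100 simulations of unchanged groups against the same maintenance arrays limma called 0 such genes. At an unadjusted p under 0.05 it called 9647 genes in the same direction at both times, against a mean of 253.5 in the simulations. These leave out the effects, and independent lists of these sizes would share 1456.6 higher and 1966.7 lower genes. Across genes, the log2 differences at 2 and 3 weeks had a Pearson correlation of 0.851, against 0.444 in the simulations, and a Spearman correlation of 0.766. Their covariance was 0.550 against a simulated 0.0122. In the simulations the groups shared the maintenance arrays, so the fitted spread of these arrays accounts for a covariance of 0.0122. This argues against their spread as the main source of the observed 0.550. An error common to all 3 maintenance arrays is not covered, and they could not be split with at least 2 in each part.

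**Figure D3:**
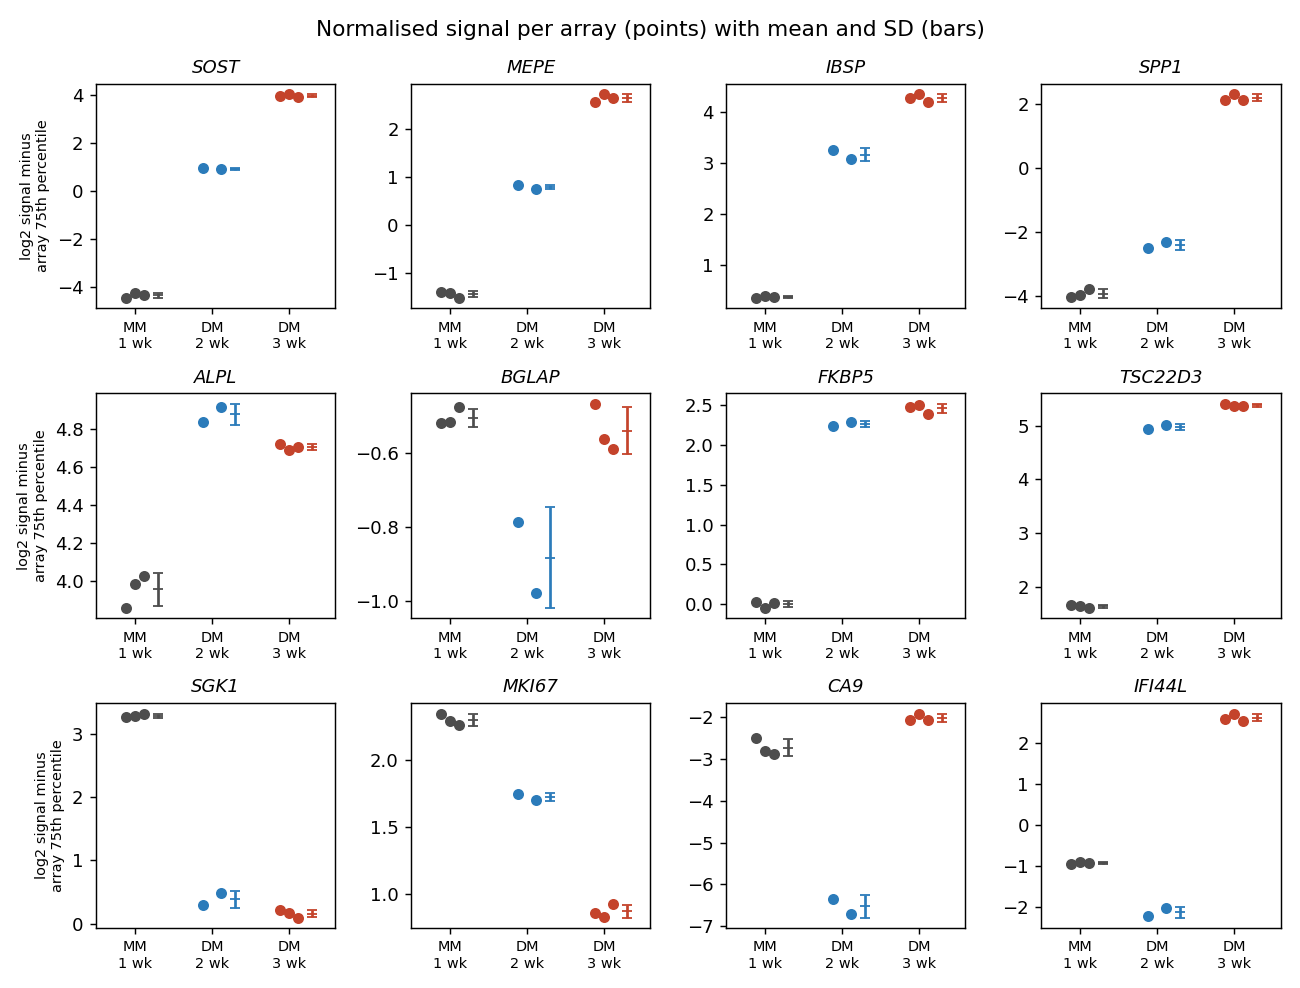
Normalised signal (log2 processed intensity minus the 75th percentile of the array, y axis) of 12 genes on each array (points) with group mean and SD (bars), for maintenance medium at 1 week (MM, n = 3) and differentiation medium (DM) at 2 weeks (n = 2) and 3 weeks (n = 3). The y axes differ between genes. SOST was higher by 5.27 at 2 weeks and 8.31 at 3 weeks, while SPP1 was higher by 1.52 and 6.13.

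The fourth comparison asked whether 3 weeks differed from 2 weeks in differentiation medium. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 5.03 ± 0.14, the interferon-induced IFI44L by 4.75 ± 0.07, SPP1 by 4.61 ± 0.11 and SOST by 3.04 ± 0.07 on the log2 scale (limma adjusted p of 1.3e-05, 2.7e-06, 6.1e-06 and 6.1e-06). CA9, a carbonic anhydrase of hypoxic cells, was at least 6.81-fold higher at 3 weeks and was not well above background on the 2-week arrays. Its normalised signal was -2.89 to -2.51 in maintenance medium, -6.71 and -6.34 at 2 weeks and -2.08 to -1.92 at 3 weeks. Most of its rise was thus a return to near the maintenance level after a low at 2 weeks. IBSP rose by 1.11 and MEPE by 1.85, and PHOSPHO1 differed by 0.053 and IFITM5 by 0.020 with no call. BGLAP rose by 0.34. The calcium-binding protein CALB1, the iron-binding protein LTF, LIPG and ACP3 (listed as ACPP) were lower by at least 2.65-fold, 5.25-fold, 2.49-fold and 2.21-fold. For CALB1 and LTF this was a return toward a low maintenance level after a high at 2 weeks. The signal of CALB1 was -7.17 to -6.97 in maintenance medium, -3.58 and -2.85 at 2 weeks and -6.56 to -6.24 at 3 weeks. That of LTF was -6.88 to -5.98, then -2.41 and -2.05, then -5.46 to -5.11. With no filter on dim probes another probe stood for ACP3, at -0.49 with no call. ZBTB26 differed by -3.27 ± 1.07 (limma adjusted p = 0.0495) and lost its call in 14 of 20 alternatives. Without 2-week replicate 1 its difference was -1.52, without 2-week replicate 2 it was -5.02 and without 3-week replicate 3 it was -3.91. The call was also lost without any 1 maintenance array or 3-week replicate 1 or 2.

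Interferon-stimulated genes rose again, 25 of 27 being higher and 0 lower at 3 than at 2 weeks (25 and 0 adjusted over the list alone, median 1.29, camera adjusted p = 1.2e-16 in limma, adjusted p = 0.269 with an estimated correlation). The antiviral gene IFIT2 rose by 1.59 and OASL by 2.31. All 38 proliferation genes fell, among them MKI67 (log2 -0.86) and the spindle checkpoint kinase BUB1 (-0.91) (0 higher and 38 lower adjusted over the list alone, median -0.89, camera adjusted p = 1.0e-21 in limma, adjusted p = 0.389 with an estimated correlation). Sterol and lipid synthesis genes fell, with 21 of 26 lower and 2 higher (22 and 2 adjusted over the list alone, median -0.55, camera adjusted p = 1.4e-08 in limma, adjusted p = 0.389 with an estimated correlation). FDFT1 was lower (log2 -0.66). Smaller shifts were called for endoplasmic reticulum stress and amino acid genes, with 12 of 25 higher and 4 lower (13 and 4 adjusted over the list alone, median 0.26, camera adjusted p = 0.0017 in limma, adjusted p = 0.50 with an estimated correlation). Clock genes had 8 of 18 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.0318 in limma, adjusted p = 0.441 with an estimated correlation). Hypoxia and glycolysis genes had 12 of 24 lower and 4 higher (12 and 4 adjusted over the list alone, median -0.15, camera adjusted p = 0.0318 in limma, adjusted p = 0.389 with an estimated correlation). Without 2-week replicate 1 these last 3 lists lost their calls, at medians of 0.12, 0.21 and -0.11, and the clock list did so also without maintenance replicate 1 or 3-week replicate 2 (0.21 and 0.16). The hypoxia list also lost its call with quantile normalization (-0.15) and with scaling to the median (-0.18), and the clock list with normexp (0.22), with no filter (0.15) and with the mean of a gene's probes (0.22).

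Osteoblast genes as a group were not called between 3 and 2 weeks, with 10 of 25 higher and 6 lower (10 and 7 adjusted over the list alone, median 0.05, camera adjusted p = 0.188 in limma). The same held for osteocyte and mineralisation genes (7 of 14 higher and 2 lower, 8 and 3 adjusted over the list alone, median 0.14, camera adjusted p = 0.116 in limma) and for collagen and matrix genes (13 of 34 higher and 7 lower, 13 and 7 adjusted over the list alone, median 0.10, camera adjusted p = 0.144 in limma). Glucocorticoid response genes had 12 of 27 higher and 5 lower (14 and 6 adjusted over the list alone, median 0.19, camera adjusted p = 0.0513 in limma). ZBTB16 rose by 0.51 and TSC22D3 by 0.40. Camera called 6 of 21 lists, and with an estimated correlation 0 (2 at an unadjusted p under 0.05), the lowest adjusted p being 0.269.

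**Figure D4:**
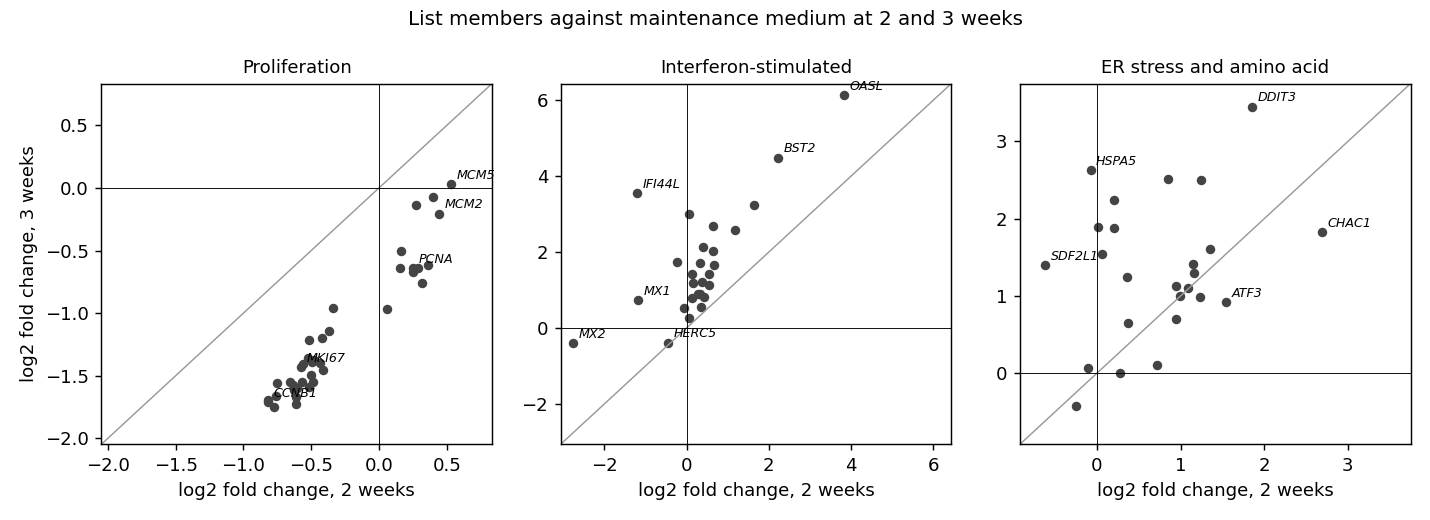
Log2 fold change of each member of the proliferation, interferon-stimulated and endoplasmic reticulum stress and amino acid lists against maintenance medium at 2 weeks (x axis) and at 3 weeks (y axis), with the line of equal change. The labelled genes were chosen after their values were seen. MCM5 and PCNA lie right of 0 at 2 weeks, HSPA5 lies at -0.07 at 2 weeks and 2.63 at 3 weeks, and IFI44L lies at -1.20 and 3.55.

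In all, limma called 8921 genes between 3 and 2 weeks, 4207 higher and 4714 lower at 3 weeks, 675 of them at 2-fold or more and 186 known only as bounds. Scaling to the median in place of the 75th percentile gave 4952, the second slide row alone, with 1 2-week array assumed to vary like the 3-week arrays, gave 4451, and normexp left 303 at 2-fold or more (421 with probes above background on all arrays).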

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

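All tests of the slide row below, that for the interferon-stimulated list included, were chosen after the data were seen. That of a rise of the whole hypoxia programme and those of the slide row for CA9 and ANGPTL4 taken separately were chosen after the result was seen. Each result of the next paragraph differed between the 2 times in differentiation medium by limma's test of 3 against 2 weeks.

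limma called 8921 genes between 3 and 2 weeks, and 72 of the 121 named genes were among them. The log2 differences furthest above 0 were 5.03 for ANGPTL4, 4.75 for IFI44L, 4.61 for SPP1, 4.50 for CA9 and 3.04 for SOST. Those furthest below 0 were -3.27 for LIPG, -3.27 for ZBTB26, -3.23 for CALB1, -3.08 for LTF and -2.93 for ACP3. CA9, LIPG, CALB1, LTF and ACP3 were not well above background at 1 of the 2 times, so their fitted values are no bounds. ZBTB26 differed by -1.52 without 2-week replicate 1, with no call, by -5.02 without 2-week replicate 2 and by -3.91 without 3-week replicate 3. Among the gene lists, the median log2 differences were -0.89 for proliferation, 1.29 for interferon-stimulated genes and -0.55 for sterol and lipid synthesis. They were 0.26 for endoplasmic reticulum stress and amino acid genes, 0.21 for clock genes and -0.15 for hypoxia and glycolysis genes. The calls of these last 3 lists were lost without 2-week replicate 1, at medians of 0.12, 0.21 and -0.11.

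The interferon-stimulated list rose from 2 to 3 weeks by a median of 1.29. An effect of the slide row was tested on the 2-week arrays, of which 1 lay beside the 3-week arrays and 1 in the other row. The array beside them was higher by a median of 0.045 (interquartile range -0.0055 to 0.12) over the members, which argues against the row as the whole cause, although it rests on 1 array per row. The lowest median was 1.26 under quantile and median scaling and 1.07 with 1 array left out, which argues against scaling and against a single array. A biological change between 2 and 3 weeks of culture stays open as a hypothesis, and whether the replicates were separate cultures is not stated.

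CA9, a member of the hypoxia list, and ANGPTL4, a known target of hypoxia-inducible factors that was in the glucocorticoid response list, rose from 2 to 3 weeks while most members of the hypoxia list did not. CA9 was lower at 2 weeks than in maintenance medium, so most of its rise was a return to near the maintenance level. ANGPTL4 was not lower at 2 weeks than in maintenance medium. The 2-week array in the row of the 3-week arrays differed from the other 2-week array by 0.29 for ANGPTL4, far below its change, which argues against the slide row for this gene, although it rests on 1 array per row. The other 23 members had a median change of -0.18 (interquartile range -0.50 to 0.02), with 3 called higher and 12 lower, which describes the pattern and is no separate test of a rise of the whole programme. The slide row stays open for CA9, which was well above background on 0 of the 2 2-week arrays. A fault of a single probe stays open for CA9 and ANGPTL4, because no other probe of either was measured. A regulator other than hypoxia is a biological hypothesis that was not tested.

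SGK1 had a log2 difference of -3.05 in differentiation medium, while FKBP5 (2.38), TSC22D3 (3.59), PER1 (1.83) and ZBTB16 (4.23) were higher. With quantile, median and normexp settings the value for SGK1 was at most -2.94, which argues against scaling as the cause. A fault of the SGK1 probe stays open, because no other probe of SGK1 was measured. A difference in how long cells were exposed to dexamethasone or had been in culture is a biological hypothesis that the design does not separate and that was not tested.

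For the count between the media, 1 of the 56 splits of the 8 arrays into 5 and 3, the real one, gave as many as 9914 genes. This is the smallest share that 56 splits allow, and it is under 0.05. Arrays of 1 group were close to each other, so splits that mixed the groups could call few genes. The share argues against chance in how these arrays were divided but cannot exclude it. If the replicates are technical, this does not extend to the spread between cultures. The highest other split, with 6776 genes, set the 3 3-week arrays against the rest, a structure of the samples. For 3 weeks against maintenance, the real split gave 13855 genes and the highest of the others 0 in limma, and 1 of 10 splits is too few for a share under 0.05.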

How the results depend on the processing

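The tests with the slide row were chosen after the data were seen, and the other alternatives were planned. Over all alternatives, 2964 values of named genes kept their direction and side of the threshold, 70 lost the call, 5 gained one and 0 turned direction. For gene lists these numbers were 1457, 54, 45 and 40, and for counts of genes 154 stayed within 1.5 times and 10 fell below. These tallies, and the alternatives counted per gene, include the deposited value table, which equals the values used and so could not differ. The slide row as a block repeats the fit without 2-week replicate 2 at 2 weeks. Between 3 and 2 weeks it repeats the fit without 2-week replicate 1. Directions of lists are those of their tests, and the values given are medians. The cause was not tested where none is given.

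Counts of called genes left that range for 3 against 2 weeks with scaling to the median (4952, of which 39.0% were higher) and with the second slide row alone (4451, with 1 2-week array). As a block, the slide row left 4420 genes called between the media, 8859 at 2 weeks, 8699 at 3 weeks and 6902 between 3 and 2 weeks, and the first row alone gave 7560 at 2 weeks. No maintenance array lay in the second row, so between the media the block leaves 1 2-week array against maintenance medium, and elsewhere the row effect rests on the 2 2-week arrays. Counts at 2-fold or more with normexp were 1310, 1106, 1688 and 303. Its offset of 50 shrinks the folds of dim probes, but it also started from raw intensities, and the share of each was not tested. With probes above background on all arrays, a filter that removes genes dim in 1 group, they were 1343 (2 weeks) and 421 (3 against 2 weeks). Leaving out each array in turn gave 7255 to 10831 genes between the media, 8859 to 10605 at 2 weeks, 12620 to 13799 at 3 weeks, 6902 to 8968 between 3 and 2 weeks, and 7348 to 8384 shared by 2 and 3 weeks. A lone remaining 2-week array was assumed to vary like the other groups. Dim probes limit folds, which are bounds for genes not above background in a group.

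Under the block of slide rows 6 lists were called between the media and 3 between 3 and 2 weeks, and the proliferation list was not called between the media (-0.48). Leaving out 1 array gave 9 to 10, 8, 10 and 3 to 7 lists in the 4 comparisons. With an estimated correlation the counts were 2, 0, 0 and 0 by camera in limma, with 4, 3, 5 and 2 at an unadjusted p under 0.05, and fry called 14, 18, 21 and 16. The estimated correlation ended the calls of the glucocorticoid list between the media (0.29), at 2 weeks (0.23) and at 3 weeks (0.36), and of the proliferation list in all 4 comparisons (-1.03, -0.49, -1.39 and -0.89). It also ended those of the osteoblast list at 2 weeks (1.30) and 3 weeks (1.20). fry does not compare a list with other genes. Between the media, where the difference between 2 and 3 weeks counted as spread, it did not call the proliferation (-1.03) and interferon-stimulated (0.92) lists. It called the collagen list in all comparisons (0.27, 0.21, 0.29 and 0.10), the osteocyte list at 2 weeks (0.032), 3 weeks (-0.13) and between them (0.14), and between 3 and 2 weeks the osteoblast (0.053) and glucocorticoid (0.19) lists. The glucocorticoid list was also called between 3 and 2 weeks with quantile normalization (0.23), scaling to the median (0.16) and probes above background on all arrays (0.19). With 1 array left out it ran from 0.17 to 0.19 and was called in 1 of the 8 fits.

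The lists whose tests turned direction were near 0 or mixed. With scaling to the median they were the osteocyte list between the media (0.0096) and the adipocyte list at 3 weeks (-0.014). With normexp they were p53 targets between the media (-0.021) and at 3 weeks (-0.029), the osteocyte list at 3 weeks (-0.071) and BMP targets between 3 and 2 weeks (0.029). With no filter they were p53 targets between the media (-0.0069) and at 3 weeks (-0.011), clock genes between the media (0.020), the adipocyte list at 3 weeks (-0.10) and BMP targets between 3 and 2 weeks (0.020). With probes above background on all arrays they were the adipocyte list between the media (-0.061), the osteocyte list at 2 weeks (-0.12) and 3 weeks (-0.27), p53 targets at 3 weeks (-0.011) and BMP targets between 3 and 2 weeks (0.020). With the mean of a gene's probes it was the osteocyte list between the media (0.049). Under the block of slide rows they were clock genes between the media (-0.013), the blood list between the media (0.083), at 2 weeks (0.083) and at 3 weeks (0.13), and the adipocyte list at 3 weeks (-0.16). With fry they were the adipocyte list between the media (-0.21) and BMP targets between 3 and 2 weeks (0.020). With 1 array left out, the ranges of lists that turned were -0.082 to -0.013 (osteocyte, media), -0.029 to 0.018 (p53, media), -0.041 to 0.0015 (p53, 3 weeks), -0.072 to -0.0026 (adipocyte, 3 weeks), -0.10 to 0.066 (adipocyte, 3 against 2 weeks), -0.22 to 0.083 (blood, 2 weeks), 0.0021 to 0.082 (BMP, 3 against 2 weeks) and -0.095 to 0.042 (endothelial and epithelial, 3 against 2 weeks).

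With the replicate number as a block, 8001, 9473, 13200 and 7480 genes and 10, 8, 10 and 5 lists were called, and 7801 genes at both 2 and 3 weeks. Deviations from group means correlated by -0.062 to 0.061 between same-numbered arrays of different groups, and by -0.11 to 0.14 between differently numbered ones. No pairing showed, but deviations sum to 0 within groups of 2 or 3 arrays, so these values cannot exclude it. The block ended the calls of PTPRC, RUNX2, SPP1 and ZBTB26, and of the hypoxia list between 3 and 2 weeks, and no other call of a named gene or list. Scaling by spike-in probes and blocks for slide and scan were not run, and the deposited value table, identical to the values used, moved nothing.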

Other observations

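No test here was chosen after its result was seen, but all genes named here other than MKI67 and CCNB1 were chosen after their values were seen. Members of the proliferation list went different ways at 2 weeks. A total of 11 were higher than in maintenance medium, among them MCM2 (log2 0.44 ± 0.05) and MCM5 (0.53 ± 0.06), subunits of the replicative helicase, the replication clamp PCNA (0.25 ± 0.04) and the cyclin CCNE2 (0.32 ± 0.04, with 0.15 and no call in its other probe). At 3 weeks 9 of these 11 were lower than in maintenance medium, with PCNA at -0.64 ± 0.03 and CCNE2 at -0.76 ± 0.04. The other 26 that were lower at 2 weeks, MKI67 and CCNB1 among them, were lower at both times.

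The endoplasmic reticulum stress and amino acid list also split. Of its 25 members, 17 were higher at both times, and the chaperones HSPA5 and HSP90B1 were higher only at 3 weeks, with log2 differences of -0.07 and 0.01 at 2 weeks and 2.63 and 1.89 at 3 weeks. The stress transcription factor DDIT3 was higher by 1.85 at 2 weeks and by 3.45 at 3 weeks. CHAC1, which degrades glutathione, and the transcription factor ATF3 were higher at 2 weeks (2.69 and 1.55) than at 3 weeks (1.83 and 0.92), but 1 of the 3 other ATF3 probes differed by only 0.09 and 0.05 with no call.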
